A study of Mus musculus with 2 samples.

How the data were processed

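Droplet single-cell RNA sequencing was deposited for 2 kidneys, 1 control and 1 IRI library, each from a wild-type mouse of 9 weeks. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0.0 against mm9 and analysed with Seurat 3.2; the annotation held here is of another build, so no coordinate is given. The first deposited table holds, for 15169 genes and 11759 cells, a score that is not a raw count: depth-corrected counts as SCTransform gives them, whole numbers whose totals per cell run from 1468 to 3212 while raw UMIs run from 271 to 24680. A second deposited table is the natural log of the same values plus 1 (largest difference 5.3e-15), and another deposited table holds residuals, also a score, for 3000 genes. The deposited annotation gives each cell's library, raw UMIs, genes, cluster (29 clusters) and cell type (18 names). It was written without separators, and the split was checked: corrected totals matched in all 11759 cells, in 3615 cells more than 1 split into raw UMIs and genes was possible and the first with at least 200 genes was kept, and raw UMIs from the split followed the Top2a residuals of 11626 cells (Spearman rho -0.998, across cells of the table).

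The raw count table was not analysed here. The plan had assumed raw counts, so these points of it changed once the tables were seen: no interval for a ratio of expression is given, 0.05 was added to each mean corrected count before the log2 ratio, cells were not thinned to a common depth, doublets were not called, and named genes were ranked by log2 ratio instead of by an interval's bound, with a least mean of 0.1 in the higher library in place of a level relative to all UMIs. The authors' subdivision of the macrophages was used instead of new subclusters. Macrophages are the types Resid. Mac, Ccr2+ Mac and Cx3cr1+ Mac, and proximal tubule is PT-S1, PT-S2 and PT-S3.

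Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of shares exact conditional 95% intervals; where a count is 0, the limit is 3 counts of the total. All cover counting error only. Types with at least 20 cells in each library were compared as the log2 ratio of IRI over control of the mean corrected count, without further scaling. A list member was measured with at least 10 summed corrected counts, and a list needed 4 measured members. Its median log2 ratio was set against 10000 random lists of the same size, matched in 10 bins of mean expression, which describes these libraries and is no test between animals. Where a gene is listed at 0 in a library no ratio is given, and medians with bounds set it to 3 counts over the group. A change of 2-fold in a mean is the limit for counting a list member.

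The named genes are, for macrophages and proximal tubule, the 12 highest and 12 lowest log2 ratios (5 for other types) among genes with at least 30 summed corrected counts, without mitochondrially encoded, ribosomal protein, haemoglobin, Gm-number and Rik genes and without genes over 10 times more abundant in the other cells. Members of the 31 gene lists are named besides. The lists and 17 sets of cell type markers were fixed before the data were examined, and 547 of their 572 genes are in the table. Any other gene named was chosen after its values were seen.

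Cells with at least 1 UMI of a rare gene were read from the deposited residuals, where cells with no UMI form a smooth curve in depth below an empty interval at least 0.5 wide. Cells in division are those with at least 2 of the G2 and mitosis genes above 0. Cells with and without an Arg1 UMI were compared within the IRI macrophages, by the same means, naming the 10 highest and 10 lowest genes and list members with 30 summed corrected counts.

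The log2 ratio, the list median, the call of cells with a UMI and the interval of a share ratio were tested on simulated data, and the other steps were not. For the simulated macrophage comparison all of 100 genes with a 2-fold change had the right direction (100%), with a median log2 of 0.84 for a true value of 1, and 96% of 200 lists of 14 unchanged genes, drawn from 7695 genes, lay within the random range. For the simulated proximal tubule comparison the direction was right for 100% of 100 genes with a median of 0.80, and 95% of 200 lists drawn from 11773 genes lay within the range. The pseudocount therefore draws ratios of scarce genes toward 0. In these comparisons gene totals were drawn as independent Poisson counts, so genes that vary together, extra spread between cells and free RNA are not covered. All simulated cells with a UMI, among 11759 cells, were found (100%), and 0 without.

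Alternatives were other scalings (trimmed mean of log ratios, median of gene ratios, totals without mitochondrially encoded, ribosomal protein and haemoglobin genes), means of each cell's own proportions, other limits, a subtraction of free RNA, subsets of cells, and a clustering of 2000 variable genes on 30 principal components with 15 neighbours (Leiden at resolution 1, 31 clusters) named from the fixed markers. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, igraph 0.11.9 and leidenalg 0.10.2.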

Results

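Single-cell RNA sequencing compared a normal mouse kidney with a kidney after ischaemia-reperfusion injury (IRI), in which blood flow to the kidney is stopped and restored, with the opposite kidney removed. The labels list 1 library per group, from wild-type C57BL/6 mice of 9 weeks, and give no time after injury. They call the control normal and name no nephrectomy for it, so ischaemia and loss of the other kidney cannot be told apart. The deposited tables held 6589 control cells with 24169073 raw UMIs (median 2344 UMIs and 911 genes per cell) and 5170 IRI cells with 16816996 raw UMIs (median 1888.5 UMIs and 716 genes). With 1 library per group there is no spread between animals and no test, so every comparison below describes these 2 libraries, and intervals are exact 95% intervals for counting error only. Expression is given as the mean depth-corrected count per cell, and cell types carry the names of the deposited annotation.

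The first comparison asked which cell types made up each kidney. Macrophages, the phagocytes of the tissue, formed 4.95% (4.44 to 5.50) of control cells and 10.5% (9.66 to 11.4) of IRI cells, 2.12 times the share (1.84 to 2.44). Immune cells together formed 6.28% of control and 15.7% of IRI cells. Neutrophils, the first blood cells drawn to damaged tissue, numbered 2 in the control and 106 in the IRI library. B cells had 3.26 times (2.06 to 5.29) and T cells 2.10 times (1.5 to 2.95) their control share, and in cells with at least 2000 raw UMIs the B cell ratio was 5.86. Proximal tubule cells of the segments S1 to S3 formed 73.3% of control and 63.1% of IRI cells, a ratio of 0.861 (0.823 to 0.900).

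Within the macrophages the makeup differed. The type named for Ccr2, the receptor that draws monocytes out of the blood, went from 0.486% (0.332 to 0.685) of control cells to 4.20% (3.67 to 4.78) of IRI cells, a ratio of 8.64 (5.94 to 13), though its 32 control cells held dendritic cell genes and are not like its IRI cells. Resident macrophages had 2.07 times their control share (1.72 to 2.50), and in cells with at least 1000 raw UMIs, where 19 control and 114 IRI resident macrophages remained, that ratio was 7.72. The type named for Cx3cr1, the fractalkine receptor of tissue macrophages, was at 1.61% of control and 0.368% of IRI cells, a ratio of 0.228 (0.132 to 0.375).

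Among tubule cells, the type named injured proximal tubule held 135 IRI cells (2.61%, 2.19 to 3.08) and 0 of 6589 control cells, which allows a share of up to 0.0455%. Proliferating proximal tubule cells formed 0.243% of control and 3.0% of IRI cells, 12.3 times the share (7.37 to 22.1). Segments S2 and S3 had ratios of 0.678 and 0.698, whereas S1 had 2.10 (1.90 to 2.33). The thick ascending limb (ratio 0.441, 0.352 to 0.548), the distal convoluted and connecting tubule (0.340, 0.253 to 0.451) and the vasculature (0.551, 0.429 to 0.703) formed smaller shares of the IRI library. Intercalated cells (1.23, 0.833 to 1.81) and myofibroblasts (1.44, 0.862 to 2.41) had intervals that include 1. In cells with at least 2000 raw UMIs the ratios were 0.365 for S2, 0.529 for the distal convoluted and connecting tubule, 47.9 for thin limb cluster 9 and 0.0365 for cluster 11. Cells named thin descending limb lay in 2 clusters that hardly overlapped between libraries: cluster 11 held 391 control and 20 IRI cells with much of the proximal tubule marker Kap (75.6 and 143.8, against 58.7 and 29.3 in S3), and cluster 9 held 36 control and 420 IRI cells. A shared library effect cannot be told from a cell type where a cluster comes almost wholly from 1 library.

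**Figure D1:**
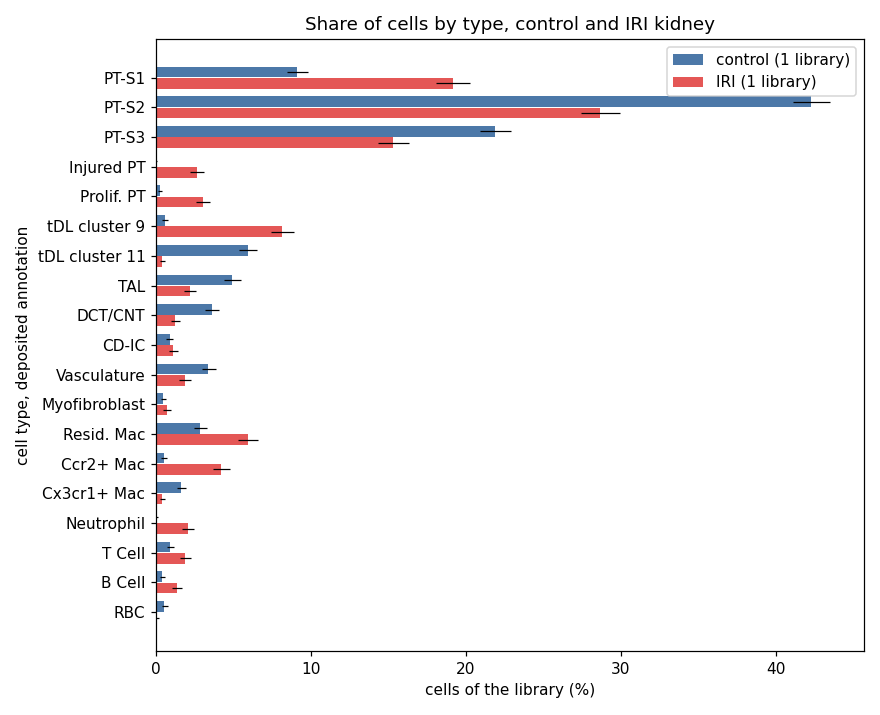
Share of each cell type among all cells of the control (blue) and the IRI (red) library in percent, with exact 95% binomial intervals that cover counting error only. Ccr2+ macrophages reach 4.20% of IRI cells against 0.486% of control cells, where the type holds dendritic cell genes, and injured proximal tubule cells appear in the IRI library alone, at 2.61%.

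The second comparison asked how macrophages differed in expression. Arg1, the enzyme that splits arginine into ornithine and urea, headed the genes higher in IRI macrophages, with a mean of 0.839 over 542 IRI cells, while it is listed at 0 in all 326 control cells. The monocyte attractant Ccl7 (0.618) and the eosinophil attractant Ccl24 (0.345) are likewise listed at 0 in the control, and Ccl2 stood at 0.923 against 0.0583. Higher still by level was Spp1, the secreted matrix protein osteopontin (4.28 against 0.270), although the other IRI cells held more of it than the macrophages did. Its means in IRI were 0.928 in T cells, 1.46 in B cells and 1.97 in neutrophils, beside 2.21 in resident and 7.51 in Ccr2+ macrophages. Fn1 (fibronectin, log2 ratio 3.36), Thbs1 (thrombospondin, 2.95), Ier3 (3.18), S100a4 (2.75), S100a6 (2.78, also more abundant in other cells), the fatty acid carrier Fabp5 (2.75) and the lysosomal protease Ctsd (2.88) complete the 12 named genes. The 12 lower genes included H2-Eb1 (-2.60), H2-Ab1 (-2.36), H2-Aa (-2.30) and their chaperone Cd74 (-2.47), which present antigen to T cells, as well as Ccl3 (-2.46), the tetraspanin Cd81 (-2.16), the glucocorticoid-induced Tsc22d3 (-2.20), Ddit4 (-2.72) and St3gal6 (-2.13). The other 3, Kap, Inmt and Mpv17l, were more abundant in other cells than in macrophages.

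Gene lists fixed beforehand gave the same contrast in groups. Of 14 measured genes of infiltrating monocytes, 12 were at least 2-fold higher (median log2 ratio 1.97, or 2.16 with genes listed at 0 set to 3 counts over the group), among them Lyz2 (2.24), Plac8 (1.79) and Ccr2 (1.42). Of 14 genes of alternative macrophage activation, the state linked to repair, 9 were at least 2-fold higher and Mgl2 lower (-1.56), with a median of 1.34; Chil3 (1.98), Msr1 (1.73) and Mrc1 (1.25) were among the higher ones. Genes of classical activation had a median of 0.31 over 16 genes, with Ccl2 and Socs3 (1.73) at least 2-fold higher and Tnf at -0.42. Class II antigen presentation had a median of -1.71, with 6 of 8 genes at least 2-fold lower. Macrophage-derived growth factors had a median of 0.83 (1.11 with bounds), with 7 of 16 genes at least 2-fold higher, including Trem2 (2.48), Osm (1.93), Grn (1.43) and Lgals3 (1.70). Lysosome and lipid handling genes had a median of 0.89 with 6 of 19 higher, and chemokines and their receptors 0.66 with 7 of 18 higher and Ccl3 and Ccl4 (-1.58) lower. Each of these medians lay outside the central 95% of 10000 random lists matched on expression.

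GM-CSF and IL-4 are cytokines that drive Arg1 in cultured macrophages. The list of their receptor pathway, which holds receptor subunits, signalling genes and ligands, had a median of 0.14, within the random range. Among the receptor subunits Csf2rb (1.49) and Il4ra (1.06) were at least 2-fold higher and Csf2ra was at 0.01. Apart from Arg1, the arginine and polyamine genes had 1 member at least 2-fold lower, Odc1, the first enzyme of polyamine synthesis (-1.09), and a list median of -0.07 that turned to 0.13 when scaled by the trimmed mean of log ratios. Odc1 is abundant in the proximal tubule and was lower there by as much (2.99 in control, 1.31 in IRI, -1.17), so its macrophage value is not separable from tubule RNA. Glycolysis genes had a median of 0.60, with Pkm (1.86), Eno1 (1.47), Pgk1 (1.21) and Ldha (1.02) at least 2-fold higher. Fatty acid oxidation genes had a median of -0.47, beside a median of -0.63 for proximal tubule transporters, which macrophages should lack.

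Because the mix of macrophage types differed, resident macrophages (cluster 7 in both libraries, 188 control and 306 IRI cells) were compared alone. Class II genes were lower there too, with a median of -2.44 and 5 of 7 genes at least 2-fold lower: Cd74 stood at 20.8 in control and 3.67 in IRI cells and H2-Aa at 5.30 and 0.804. Complement C1q genes, markers of these cells, were not lower (C1qa 0.38, C1qb 0.81, C1qc 0.67). Infiltrating monocyte genes were higher (median 1.78, 6 of 9 at least 2-fold), led by S100a6 (2.86), S100a4 (2.64) and Lyz2 (2.07), as were chemokines and their receptors (1.00, with Ccl12 at 2.38) and interferon response genes (0.69, with Ifi27l2a at 1.31). Hmox1, which breaks down haem, stood at 0.278 against 0.0160 (2.31). These cells were shallow, with medians of 599.5 and 799.5 raw UMIs, and the median of all measured genes was 0.17; the scaling with the strongest effect takes off 0.21, which turns none of the directions given here. The Ccr2+ type allows no such comparison, since its 32 control cells held dendritic cell genes (Cd209a 1.75, Siglech 1.03) and listed C1qb at 0, whereas its 217 IRI cells had means of 0.180, 0.0415 and 4.06.

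Division genes were higher in resident macrophages of the IRI library. The G2 and mitosis list had a median of 1.26 (1.96 with bounds), with 11 of 15 genes at least 2-fold higher, and the S phase list 1.04. Cells with at least 2 of these mitotic genes formed 1.60% (0.330 to 4.59) of control and 25.2% (20.4 to 30.4) of IRI resident macrophages, a ratio of 15.8 (5.20 to 78.1), which was 5.49 with at least 1 gene and 30.1 with at least 3. In IRI Ccr2+ macrophages the share was 10.6% (6.84 to 15.5), beside 12.5% (3.51 to 29.0) of the 32 control cells. The proximal tubule segments S1 to S3 had 0.124% in the control and 1.35% in the IRI library, at median depths of 2738 and 1819 raw UMIs. That is a ratio of 10.9 (4.61 to 31.2), which was 1.45 with at least 1 gene. These shares leave out the cells that the annotation names proliferating proximal tubule, of which 96 of 155 in IRI (61.9%) were in division. Over all epithelial cells the share was 0.340% in the control and 4.74% in the IRI library. IRI neutrophils, which should not divide, had 5 of 106 (4.72%, 1.55 to 10.7) at a median of 1451 UMIs.

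**Figure D2:**
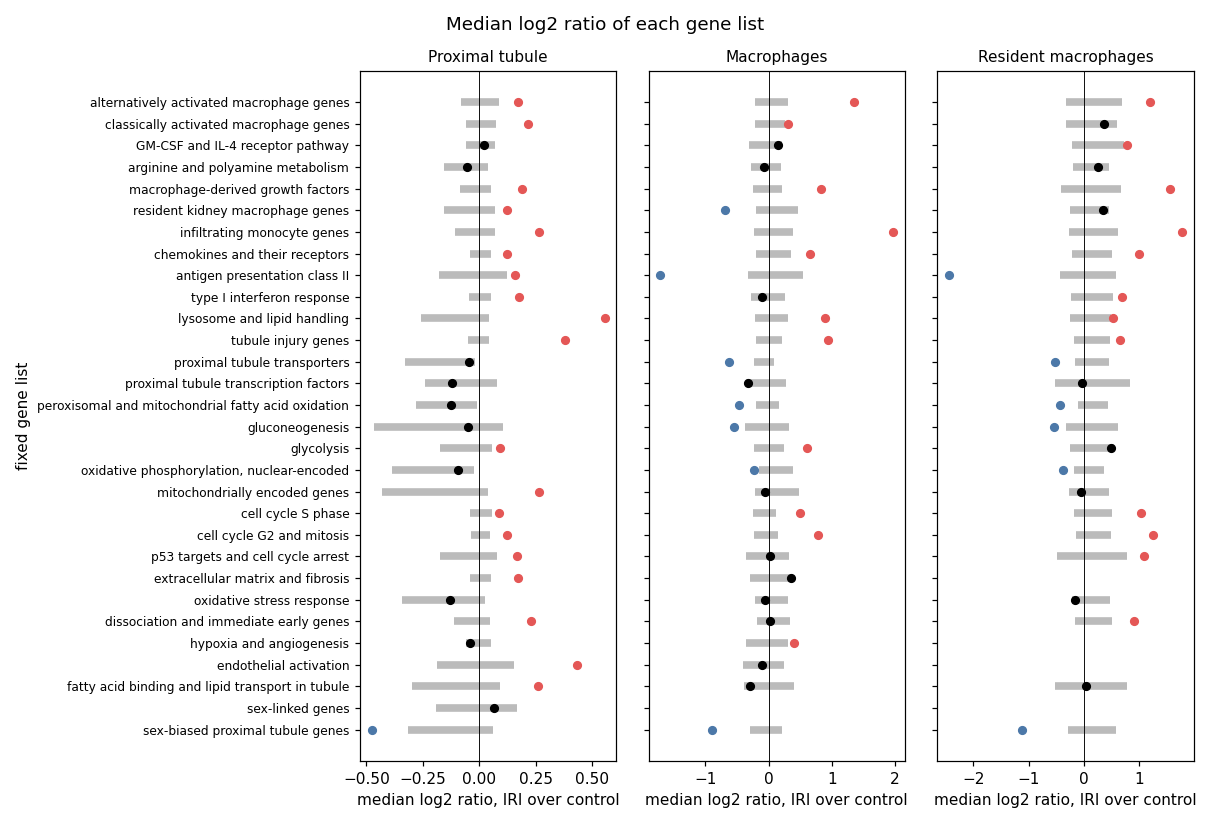
Median log2 ratio (IRI over control) of each fixed gene list in proximal tubule cells, all macrophages and resident macrophages. Grey bars span the central 95% of 10000 random lists matched on expression, and points are red above, blue below and black within them; class II genes lie at -1.71 in all macrophages and -2.44 in resident macrophages, and infiltrating monocyte genes at 1.97 and 1.78.

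The third comparison asked which cells held Arg1, the gene in the series title. A UMI of Arg1 was found in 122 of 5170 IRI cells and in 0 of 6589 control cells, which allows up to 0.0455%. In the IRI library 60 of 217 Ccr2+ macrophages had one (27.6%, 21.8 to 34.1), as did 12 of 306 resident macrophages (3.92%, 2.04 to 6.75) and 0 of 19 Cx3cr1+ macrophages. The median depths of the Ccr2+ and resident types were 7177 and 799.5 raw UMIs, and per 1000000 raw UMIs the 2 types had 36.4 (27.8 to 46.9) and 24.3 (12.6 to 42.5) such cells, a rate that levels off in deep cells with many Arg1 UMIs. The mean depth-corrected counts were 1.96 and 0.0980, and in the alternatives run the shares ranged from 25.3% to 27.8% and from 3.59% to 6.14%. In control macrophages 0 of 326 cells had a UMI, which allows up to 0.920%, and only 32 of these cells were of the Ccr2+ type. T cells, which should lack Arg1, had 0 of 97 at a median of 3345 UMIs, while vasculature had 2 of 96 (11.9 per 1000000 raw UMIs, 1.44 to 42.8; median 1131 UMIs) and neutrophils 2 of 106 (12.4 per 1000000, 1.5 to 44.7; median 1451 UMIs). Proximal tubule cells had 33 of 3261 (1.01%, 0.698 to 1.42; 1.63% of those with at least 2000 UMIs) at a median of 1819 UMIs, or 3.31 per 1000000 UMIs, and injured proximal tubule cells 6 of 135 (4.44%, 1.65 to 9.42) at 8267 UMIs, or 5.54 per 1000000.

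**Figure D3:**
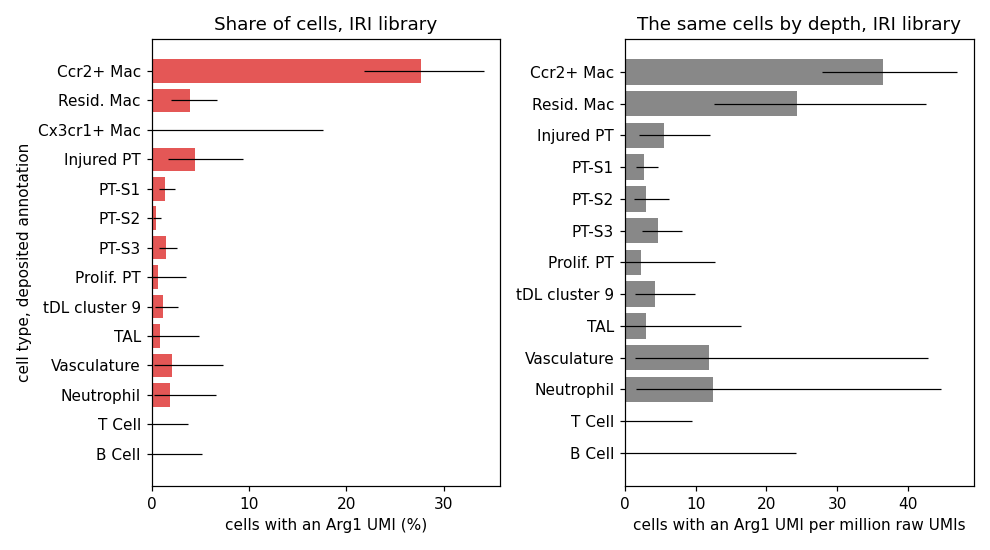
Left, share of IRI cells of each type with an Arg1 UMI in percent, with exact 95% binomial intervals; right, the number of such cells per 1000000 raw UMIs, with exact 95% Poisson intervals. Ccr2+ macrophages stand at 27.6% and 36.4 per 1000000, and segments S1 to S3 of the proximal tubule between 2.76 and 4.65 per 1000000.

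Within the IRI library, the Ccr2+ macrophages with an Arg1 UMI (60 cells, median 8290 UMIs) had a different profile from those without (157 cells, median 6879 UMIs). Ccl24 had means of 3.07 and 0.00637, a log2 ratio of 5.79, and Cxcl3 a mean of 0.883 against a listing at 0. Spp1 (3.63), Fn1 (2.88), Cxcl2 (2.84), Thbs1 (2.67), Clec4n (2.59), Ccl6 (2.56), Ccl7 (2.48) and Ninj1 (2.45) were also higher, and so were the lysosomal proteases Ctsl (2.22) and Ctsd (2.17), the scavenger receptor Msr1 (2.11), the interleukin-1 antagonist Il1rn (2.09) and Trem2 (1.64). Infiltrating monocyte genes went both ways, with a list median of -0.02 over 13 genes within the random range: Fn1 and Thbs1 were higher, while Plac8 (0.800 against 7.28) and Ly6c2 (0.10 against 0.745) were lower. Listed at 0 in cells with an Arg1 UMI were Ccl17 and Ccl22, which attract T cells (0.656 and 0.484 in the others), the dendritic cell marker Cd209a (0.248), Ace (0.344), Cd7 (0.331), Adgre4 (0.248), Traf1 and Rasgrp2 (both 0.274), and Tspan13 stood at 0.0333 against 0.452. Class II genes had a median of -1.80 over 7 genes, in a comparison where cells without an Arg1 UMI include some with dendritic cell genes. Members of the alternative activation list went both ways: of those named above, Ccl24 and Msr1 were higher and Ccl17 and Ccl22 lower, while Mrc1 (0.28) and Chil3 (0.09) differed by under 2-fold. The cytokine receptor subunits Il4ra (0.51), Csf2ra (0.32) and Csf2rb (0.02) also differed by under 2-fold. Over all IRI macrophages, with 72 cells against 470 at median depths of 7559.5 and 1481 UMIs, the infiltrating monocyte list had a median of 1.11, and in those with at least 2000 UMIs 0.31, within the random range. Lacking a UMI does not mean lacking Arg1.

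The fourth comparison asked how proximal tubule cells of segments S1 to S3 differed. The types named injured and proliferating proximal tubule are left out, so their injury genes do not enter these values. Spp1, a secreted marker of tubule damage, had a mean of 0.20 in 4827 control and 5.62 in 3261 IRI cells (log2 ratio 4.51), and was more abundant in the other IRI cells. Other named genes higher in IRI were Cpn1 (a carboxypeptidase subunit, 2.44), Wfdc2 (2.34), Cox6b2 (2.05), Ly6e (1.79), the uncoupling protein Ucp2 (1.76), B2m of class I antigen presentation (1.71), Cyr61 (1.67), the fatty acid hydroxylase Cyp4a14 (1.64), the lysosomal protease Lgmn (1.63), the sulfate transporter Slc13a1 (1.52) and Fam25c (1.52). Of these Wfdc2, Ly6e, Ucp2 and B2m were more abundant in other cells. Lower were Inmt (-3.63), Dnase1 (-3.07), the S3 transporter Slc7a13 (-2.59), Dnajc12 (-2.42), the organic anion carrier Slco1a1 (-2.31), Gadd45g (-2.13), lipoprotein lipase Lpl (-1.99), Npm3 (-1.92), Ddit4 (-1.88), Slc22a7 (-1.87), the clock output gene Dbp (-1.87) and the tyrosine-degrading enzyme Hpd (-1.85).

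All 30 tubule injury genes were measured and had a median of 0.38 (0.44 with bounds). With 0.05 added to each mean, 5 were at least 2-fold higher: Spp1, S100a6 (2.55), complement C3 (1.41), Havcr1, which encodes KIM-1 (1.32), and Lcn2, which encodes NGAL (1.1). Scarce members can differ and stay under this limit. Vcam1 had means of 0.000414 in control and 0.0221 in IRI, with UMIs in 2.45% of IRI proximal tubule and 2.06% of IRI T cells. Sox9 UMIs were found in 0 of 4827 control and 46 of 3261 IRI cells, and Krt20 UMIs in 0 and 21. Lcn2 UMIs were found in 5.89% of IRI proximal tubule cells and 5.15% of IRI T cells, at median depths of 1819 and 3345 UMIs. Its means were 0.0573 and 0.0412, beside 2.48 in IRI thin limb cluster 9, so its proximal tubule value is not separable from free RNA. Lysosome and lipid handling genes had a median of 0.55, with Apoe (1.38), Lgals3 (1.22), Ctsb (1.18), Ctsd (1.03) and Npc2 (1.01) at least 2-fold higher and Lpl lower. The 26 transporters had a median of -0.04 that turned to 0.22 when scaled by the median of gene ratios; Slc7a13, Slco1a1, Slc22a7, Slc5a8 (-1.18) and Slc22a30 were at least 2-fold lower, Slc13a1 higher, and Slc34a1 (-0.09) and Lrp2 (0.14) near 0. Genes that differ between the sexes in this segment had a median of -0.48, with 5 of 13 at least 2-fold lower, including the androgen-regulated Kap (-1.44) and Cyp7b1 (-1.35). The mix of segments differed between the libraries, with S1 making up 600 of 4827 control and 989 of 3261 IRI cells, and within segments the sex-biased median was 0.05 in S1, -0.29 in S2 and -1.03 in S3, where the first 2 lie within the random range, and Kap was at -0.59, -1.54 and -1.0. The list median of injury genes was above 0 within each segment (0.48 in S1, 0.35 in S2 and 0.60 in S3). Mitochondrially encoded genes had a median of 0.26. Of 32 fatty acid oxidation genes, Acadm (-1.22) and Cyp4b1 (-1.01) were at least 2-fold lower and Cyp4a14 higher, with a median of -0.13 that turned to 0.13 when scaled by the median of gene ratios. That scaling takes a factor of -0.26 (log2) off every ratio of this class, and in macrophages the trimmed mean of log ratios takes off -0.20.

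The differences were wider in segment S3, the part most exposed to ischaemia. Spp1 stood at 0.0888 in 1442 control and 13.9 in 790 IRI cells (6.66), and 10 of 25 measured injury genes were at least 2-fold higher (median 0.60), among them C3 (2.29), Tnfrsf12a (1.47) and Vcam1, which is listed at 0 in the control and at 0.0557 in IRI. Transporters had a median of -0.67 with 8 of 26 at least 2-fold lower, including Slc27a2 (-1.16) and Aqp1 (-1.25), and 3 higher, and the scaling with the strongest effect in S3 takes off -0.18, which leaves these 2 medians on their side of 0. Havcr1 UMIs were found in 1 of 1442 control (0.0693%) and 105 of 790 IRI cells of S3 (13.3%, 11 to 15.9; median 2338.5 UMIs), and in 65 of 135 injured proximal tubule cells (48.1%, 39.5 to 56.9). Among IRI T cells 5 of 97 had a Havcr1 UMI (5.15%, 1.69 to 11.6, median 3345 UMIs). Different clusters held S3 in the 2 libraries: cluster 3 held 127 control and 727 IRI cells, cluster 4 held 742 and 58, and cluster 8 held 455 and 4. The S3 cells also differed in the nuclear RNA Malat1, at 46.9 in control and 4.03 in IRI. In S2, cluster 0 held 391 control and 1092 IRI cells and cluster 1 held 1283 and 25.

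Other cell types were summarised by leading genes and members of the fixed lists. Endothelial cells of the vasculature had more Lrg1 (0.802 against 0.0405, log2 ratio 3.23), an inducer of vessel growth, more Ptn (2.84) and more Igfbp7 (1.79). Myofibroblasts, with 31 control and 35 IRI cells, had more of the protease inhibitor Timp1 (3.30), of Col15a1 (3.46) and of the collagens Col3a1 (1.79) and Col1a1 (1.62), and far less of the renin gene Ren1 (7.10 in control, 0.0286 in IRI, -6.51). With so few cells, a different mix of cells under this name is not excluded. The thick ascending limb had more Lcn2 (2.42, also more abundant in other cells) and Clu (2.11), but also more of the distal tubule markers Slc12a3 (0.281 in control, 0.527 in IRI) and Pvalb (0.25 and 0.589) and less of its own Umod (12.7 and 8.96) and Egf (6.52 and 1.91). Intercalated cells had more of the antimicrobial peptide Defb1 (2.57), with less of the type B marker Slc26a4 (2.0 and 0.745) and more of the type A marker Slc4a1 (0.263 and 0.418). A different mix of cells is excluded in neither type. In the distal convoluted and connecting tubule Sprr2f is listed at 0 in the control and had a mean of 0.524 in IRI. The type named T cells had more Cd8b1 (2.50) and Cd8a (1.84), the chains of the co-receptor of cytotoxic T cells, but it also held natural killer cell genes, with lower means in IRI (Gzma 3.76 in control and 1.89 in IRI, Nkg7 3.80 and 2.85, Klrk1 1.05 and 0.649), so a different mix of cells is not excluded. Cluster 9 of the cells named thin descending limb had 107 of 420 IRI cells with a Havcr1 UMI (25.5%, 21.4 to 29.9; median 1496 UMIs), while its 36 control cells held the collecting duct channel Aqp2 (5.33 against 0.164 in IRI), so its 2 libraries do not hold like cells.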

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

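The tests on class II genes, the depth test on tubule genes and the rate of Arg1 in tubule cells were chosen after the result was seen; the correlation test and the test for mixed droplets were set beforehand. Each pair of values below was singled out because the same gene list went opposite ways in 2 cell types, IRI against control, beyond the central 95% of random lists in both; with 1 library per group the difference was not tested. Median log2 ratios were 0.56 in segment S3 and -2.44 in resident macrophages for class II antigen presentation, 0.92 in resident macrophages and -1.37 in intercalated cells for immediate early genes, 1.46 in T cells (4 genes measured) and -1.77 in myofibroblasts (7 genes) for genes of resident kidney macrophages, and 3.28 in T cells and -4.45 in the vasculature for haemoglobin genes. The T cell haemoglobin counts came from 1 cell. Over the whole proximal tubule Cd74 had means of 0.124 in control and 0.144 in IRI, beside 0.169 and 0.165 in T cells. Tubule class II values are therefore not separable from free RNA. The T cell value for resident macrophage genes also rests on low means, such as C1qa at 0.0169 in control and 0.124 in IRI.

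Class II genes were lower in IRI resident macrophages. In cells with at least 1000 raw UMIs (19 control, 114 IRI) the median was -2.25, so the depth correction of shallow cells is not the cause. Free RNA is not either, since control T cells held 0.814% of the Cd74 of control resident macrophages. The other resident macrophage genes had a median of 0.48 (10 genes), against a loss of resident cells, yet infiltrating monocyte genes were higher too; cells from blood monocytes under the same name and lower class II expression in resident cells cannot be told apart with 1 time point. Lower expression after injury stays open as an untested biological explanation.

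Tubule transcripts were lower in IRI lymphocytes. The 54 tubule genes used had a mean of at least 1 in the proximal tubule of each library. Their higher tubule mean was at least 5 times their higher lymphocyte mean, which was at least 0.1. Not all of them are absent from lymphocytes by nature, as with Ftl1 (5.50 in control and 5.55 in IRI lymphocytes). Across 54 tubule genes the log2 ratios in lymphocytes (86 control, 166 IRI cells) followed those in the proximal tubule (Spearman rho 0.667, with genes as the units), with medians of -0.45 and -0.37. Free RNA from the tubule may account for this, but the correlation cannot tell it from a change that both cell types share. The depth correction of shallow cells is not the whole cause: in lymphocytes with at least 2000 raw UMIs (58 and 128 cells) the median of the 54 genes was -0.46 (-0.65 to -0.17 by resampling genes) and 42 were lower. Tubule genes that differ in any other cell type, higher ones such as Spp1 included, are best read with this in mind.

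Arg1 UMIs occurred in 33 IRI proximal tubule cells. Droplets with a tubule cell and a macrophage are not the source: these cells held 1.02% of the macrophage marker counts of Ccr2+ macrophages (0.576 against 56.4), beside 0.517 in tubule cells without an Arg1 UMI, at median depths of 5771 and 1806.5 UMIs. Their rate per raw UMI was 0.822 times (0.292 to 3.19) that of the cells that are neither epithelial nor macrophages, of which 4 of 407 had an Arg1 UMI. With so few cells, free RNA and a low level of Arg1 in tubule cells cannot be told apart.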

How the results depend on the processing

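The settings with at least 2000 raw UMIs, with 0.5 added for lists, on resident or Ccr2+ macrophages alone and all those for Arg1 were chosen after seeing the data. Of 138 values for leading results under alternatives set before the data were seen, 114 stayed within the counting interval or moved by less than that of random lists, 24 moved further and 0 reversed; under added ones 72 of 109 stayed, 36 moved and 1 reversed. A change of side counts as reversed only for a share ratio or list median outside its interval, or for a single gene, so the transporter median (-0.04 to 0.22), which lay inside, counts as moved. Other results gave 467 of 577 and 375 of 472 within these limits. The share ratio of Ccr2+ macrophages ran from 8.69 to 9.50, that of Cx3cr1+ macrophages from 0.221 to 0.237 and that of S1 from 2.05 to 2.15. These settings all keep the deposited names. The new clustering, not used for these ratios, split Ccr2+ cells into a macrophage cluster (10 control, 177 IRI cells) and one named dendritic cell (22 and 37). Except where the construction shows it, the cause was not tested. Share ratios with at least 1000 raw UMIs were 0.814 for proximal tubule, 2.87 for macrophages, 0.511 for S2, 7.72 for resident macrophages and 23.3 for thin limb cluster 9, and the Arg1 share of macrophages was 19.3%. With at least 2000 they were 0.790, 2.73, 0.365, 7.70 and 47.9, with S3 at 0.588, thick ascending limb 0.563, distal tubule 0.529, thin limb cluster 11 at 0.0365 and B cells 5.86; the Arg1 shares were 22.4% in macrophages and 1.63% in proximal tubule; list medians were 0.71 (lysosome), 0.49 (injury) and 0.14 (transporters) in proximal tubule and 1.94 (alternative activation), 1.09 (growth factors) and, reversed, 0.11 (oxidative phosphorylation) in macrophages. With under 30% mitochondrial counts share ratios were 2.44 for macrophages, 0.566 for S2, 2.56 for resident macrophages and 0.0271 for thin limb cluster 11. Scaled by the median of gene ratios, proximal tubule medians were 0.82 (lysosome), 0.64 (injury), 0.22 (transporters) and -0.22 (sex-biased); by totals without mitochondrially encoded, ribosomal protein and haemoglobin genes 0.72, 0.55 and 0.12 for lysosome, injury and transporters; by the trimmed mean of log ratios the macrophage G2 and mitosis median was 0.99. Adding 0.5 draws ratios of scarce genes to 0 by construction: 0.16 (lysosome), 0.048 (injury) and -0.20 (sex-biased) in proximal tubule, and in macrophages 0.36 (alternative activation), 0.18 (growth factors), 0.76 (infiltrating), 0.15 (chemokines), 0.14 (lysosome) and 0.11 (G2 and mitosis). With at least 50 summed counts, which leaves fewer genes, medians were 0.48 (injury) in proximal tubule, and 1.71 (alternative activation), 1.76 (growth factors), -2.30 (class II) and 1.46 (G2 and mitosis) in macrophages. With at least 1 summed count the endothelial activation list in proximal tubule reversed to -0.000234. Resident macrophages alone gave 1.57 (growth factors), 1.00 (chemokines), -2.44 (class II), 0.53 (lysosome), 1.26 (G2 and mitosis) and, reversed, 0.35 (resident macrophage genes). With at least 1 mitotic gene the ratio of dividing shares was 1.45 in proximal tubule (10.9 with at least 2) and 2.04 in macrophages (4.41); in resident macrophages it ran from 5.49 to 30.1 (15.8). Between macrophages with and without an Arg1 UMI, the Ccr2+ type alone gave -1.80 (class II), 1.22 (lysosome) and, reversed, -0.017 (infiltrating), and cells with at least 2000 raw UMIs 1.11 (lysosome) and 0.31 (infiltrating). No paired analysis was possible because each group has 1 library and nothing pairs them. Not run, since raw counts were not analysed here, were Scrublet doublet calls and thinning to 500, 1000 or 2000 UMIs; macrophage subclusters at other resolutions were not made, because the deposited types were used. Depth limits resident macrophages most, with medians of 599.5 and 799.5 raw UMIs.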

Other observations

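The clock genes here were chosen after their values were seen. Dbp, a transcription factor driven by the circadian clock, was lower in IRI cells of types as unlike as the proximal tubule (-1.87), the thick ascending limb (-2.01), the distal convoluted and connecting tubule (-1.68), the vasculature (-1.41), myofibroblasts (-2.46) and T cells (-1.2); in intercalated cells it had a mean of 0.632 in the control and is listed at 0 in IRI. Its relative Tef was lower in the thick ascending limb (-1.41), intercalated cells (-2.01) and resident macrophages (-1.57). In the vasculature Per1 stood at 0.131 and 0.0313 and Nr1d1 at 0.230 and 0.135. The labels give no hour of sampling, so the hour and the injury are not separable with 1 library per group.

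Injured proximal tubule cells, absent from the control, carried genes of dedifferentiated tubule: Vcam1 UMIs in 31.9% of 135 cells, Sox9 in 17.0% and Krt20 in 8.15%, at a median of 8267 UMIs. In IRI T cells, at a median of 3345 UMIs, these shares were 2.06%, 0 and 0. Genes on the Y chromosome were present in both libraries (Ddx3y 0.0637 and 0.0456, Eif2s3y 0.0502 and 0.0534), so both held male cells, and the lower sex-biased tubule genes do not come from a female animal.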
